A study of Mus musculus with 18 samples.

How the data were processed

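RNA was sequenced from 18 libraries of MOVAS cells, a mouse aortic vascular smooth muscle cell line, in 6 groups of 3. Per the labels' protocols, polyadenylated RNA was captured from total RNA with poly-T beads, broken into fragments, copied into cDNA from random primers, size-selected and amplified by PCR. The protocols do not state whether the kit kept strand. Doses and treatment times are not given in the sources used here. Tools named per the submitters' processing notes are fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1, without a role for each. The genome build is not given in the sources used here, so coordinates are printed as in the deposited table.

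The deposited table holds a whole-number read count per gene and library, named a read count per the file headers, without normalization. The same deposited table holds FPKM values for each library, made by the authors. Every FPKM value (100%, within a relative difference of 1e-06) equalled the count times 1000000000 over the product of gene length and the library's column total. The table has 21959 genes, of which 51, holding 0.0187% of the counts, have a gene identifier but no symbol and were kept under the identifier. Columns were matched to samples by title, and 0 columns belonged to samples outside the series. Totals ran from 12859609 to 23284077 counts per library.

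Groups came from the sample titles. The isoliensinine groups B_I, H_I and D_I were read as the isoliensinine arms of Blank, H2O2 and Dox. The series' design text speaks of biological replicates, so p-values measure the spread between those. The chi-square statistic per degree of freedom between replicates of a group was 5.51 at the lowest, and no library was treated as a repeat of another.

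Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter on the groups (13375 tested), scaled by trimmed means of M-values (TMM), and tested by edgeR's quasi-likelihood test with robust dispersions in a model of all 18 libraries with a mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM values as mean ± SD over n = 3 libraries. SE is an approximate standard error of the log2 fold change, its absolute value over the square root of the quasi-likelihood F statistic. The 95% intervals were built from it. The biological coefficient of variation was 0.219, the median SE per gene was 0.228 to 0.231 in the comparisons of a pair of groups, and the median half-width of the 95% interval was 0.474 to 0.482.

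Dox and H2O2 were each compared with Blank and with each other, and B_I, D_I and H_I with Blank, Dox and H2O2. Differences between isoliensinine effects were tested as interaction contrasts. A set of 30 gene lists was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Lists with under 5 tested genes were not tested as lists. Camera with an estimated correlation and fry, which asks only whether a list's genes move on balance in a direction, were run beside it.

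Named genes followed a rule. In the 5 comparisons with Blank, Dox or H2O2 as the reference it took the 6 higher and 6 lower genes with the largest change among called genes with separate replicates and a mean of at least 5 FPKM in the higher group. It also took up to 4 members of each called list in that list's direction, up to 2 called members of each other list, and 14 genes fixed in advance, of which Il6 did not pass the expression filter. For Dox against H2O2 it took the 3 largest changes each way. The groups, main test, lists and naming rule were set before the data were examined.

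Alternatives were DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes reaching 1 FPKM, DESeq2 size factors, upper-quartile scaling, no filter, a filter of 5 CPM in 3 libraries, fits of only the groups compared, a replicate block, stricter thresholds, and leaving out each library. Chosen after seeing the data were fits without Blank_4 and B_I_3 or without these and H2O2_3 and H_I_1, comparisons of D_I and H_I with Blank and B_I, the mean isoliensinine effect, gene ontology terms of the deposited annotation, genes named from the 6 libraries of D_I and Dox, and simulated counts with no isoliensinine effect. The pipeline was tested on simulated data, in which 200 genes were changed by known folds at the real means and library sizes. For a 2-fold change it called 52.2% of such genes in Dox against Blank, 50.7% in H2O2 against Blank, 52.2% in B_I against Blank, 62.7% in D_I against Dox, 55.2% in H_I against H2O2 and 56.7% in Dox against H2O2. Histone genes, many without poly-A tails, and genes with close copies (histones, ribosomal protein genes, H2 and Raet1 genes) are uncertain, because reads may be split between copies. Antisense genes were not named.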

Results

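Gene expression was measured by RNA sequencing in cultured mouse aortic smooth muscle cells of the MOVAS line, in 18 libraries of 12859609 to 23284077 counts each. Untreated cells (Blank), cells given hydrogen peroxide (H2O2), an oxidant, and cells given doxorubicin (Dox), a DNA-damaging anthracycline, made 3 groups. The other 3 groups, titled B_I, H_I and D_I, are labelled only as given isoliensinine, a plant alkaloid. They were read here as the isoliensinine arms of Blank, H2O2 and Dox, because the titles run in parallel. The design text names doxorubicin and H2O2 as inducers of cell senescence. The title of the series asks whether isoliensinine helps natural killer (NK) cells, lymphocytes that kill stressed cells, to clear senescent smooth muscle cells. Each group had 3 libraries.

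In a principal component analysis of log CPM, the first component (23.5% of variance) had Blank_4 (-69.71) and B_I_3 (-61.32) at its low end. Blank_1 and Blank_2 lay at -5.96 and -14.07, while B_I_2 (-36.23) lay nearer to B_I_3 than to B_I_1 (-1.18). Acta2, which encodes smooth muscle actin, stood at 4514 CPM in Blank_4 against 806 and 901 in Blank_1 and Blank_2, and at 3875 CPM in B_I_3. Ribosomal protein genes took 11.5% of counts in Blank_4 and 11.1% in B_I_3, and 7.48% to 9.85% in the 16 others. Depth differed by group, with 20140802 to 23284077 counts in the Dox libraries and at most 17955971 in any other. With counts thinned to equal depth, 15060 to 15368 genes had a count in Dox and 14907 to 14995 in D_I. The ranges were 13331 to 14293 in Blank, 13597 to 14369 in B_I, 13732 to 14152 in H2O2 and 14718 to 15101 in H_I. Colon and liver transcripts were also present. Muc2, Lypd8, Car1, Dmbt1 and Ceacam1 summed to 640 CPM in H_I_1 against 188 and 242 in its group, and to 143 CPM in H2O2_3 against 48.6 and 37.3.

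**Figure D1:**
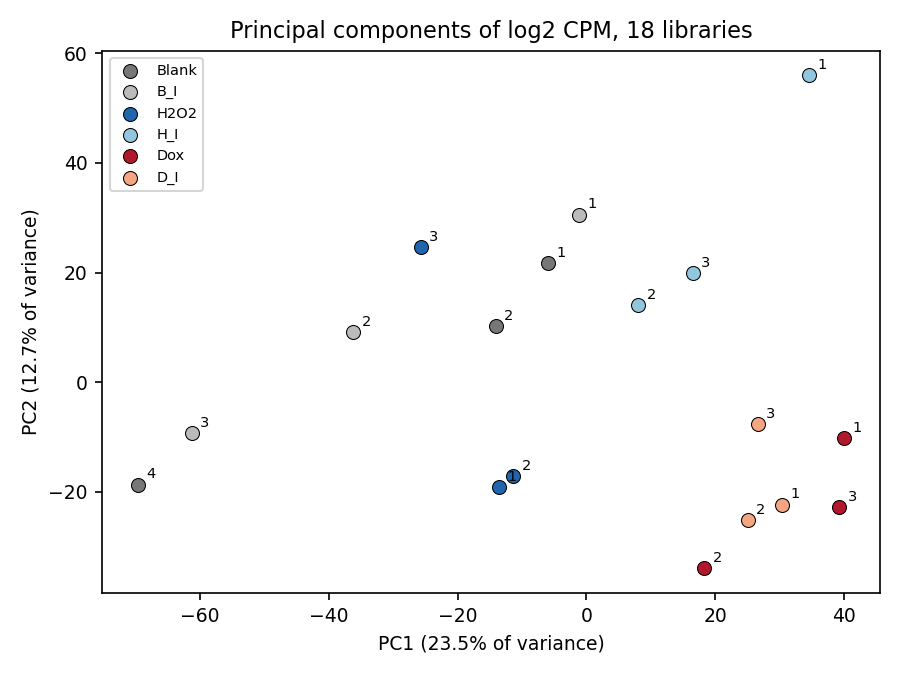
Principal components of log CPM over the 18 libraries, with the share of variance on each axis (23.5% and 12.7%), colour for the group and a replicate number at each point. Blank_4 and B_I_3 sit at the low end of the first axis, at -69.71 and -61.32, and B_I_2 is next at -36.23.

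The comparison of Dox with Blank asks what doxorubicin changed. Genes that p53, the damage-activated transcription factor, is known to switch on rose: 18 of 30 were higher and 1 lower (22 and 1 adjusted over the list alone). Cdkn1a, which encodes the cell-cycle inhibitor p21, rose 4.59-fold, from 99.4 ± 10 to 456 ± 64.0 CPM (SD, n = 3; log2 2.20, SE 0.127; edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 4.36e-10). Btg2 (log2 1.61), Aen (1.58) and Zmat3 (1.32), other p53 targets, also rose. Interferon-stimulated genes rose as well, with 22 of 48 higher and 0 lower (24 and 0 adjusted over the list alone). Oas1a, an antiviral sensor of double-stranded RNA, went from 3.85 ± 2.25 to 25.1 ± 4.52 CPM (SD, n = 3), and Dhx58 (log2 1.56), Isg15 (1.49) and Irf7 (1.47) rose with it. In the cell-cycle and mitosis list 17 of 35 were higher and 1 lower (19 and 1 adjusted over the list alone), including the mitotic kinases Aurka (log2 0.97), Cdk1 (0.88) and Bub1b (0.82). Mki67, a proliferation marker, was not called (log2 0.39, SE 0.219, edgeR adjusted p = 0.226), but was without Dox_2 (0.65, 0.0246; 0.0246 to 0.688 over all alternatives). Camera gave these lists adjusted p of 4.76e-16, 2.82e-12 and 4.91e-10, and all 3 held with an estimated correlation (adjusted p = 1.47e-05, 0.04 and 0.04).

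By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2896 of 13375 genes (21.7%) were called, 1372 higher and 1524 lower, of which 620 changed over 2-fold. Under the naming rule for large changes (separate replicates, at least 5 FPKM in the higher group), the steepest rise was that of Sprr1a. This cornified-envelope protein gene (ENSMUSG00000050359, chromosome 3, 92391259 to 92393202) rose 68.4-fold, from 0.39 ± 0.1 to 27.4 ± 4.12 CPM (SD, n = 3). Akr1c18 (42.6-fold), the carboxylesterase gene Ces2e (36.4-fold), Tigit (23.6-fold), Pierce1 (10.6-fold) and Anxa8 (7.34-fold) followed. In Blank, Akr1c18, Tigit and Pierce1 averaged 0.165, 0.352 and 0.484 CPM. The folds of these 3 genes, like that of Sprr1a, rest on few counts in Blank. Without Dox_3 the count fell to 1876. On log2(FPKM + 1) limma called 3675 genes, 2625 higher and 1050 lower, and on log2(FPKM + 0.1) 3598, 2550 higher and 1048 lower, with the median of all genes at 0.18 and 0.23 against 0.08 in the edgeR fit.

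Large losses after doxorubicin included matrix genes. Fmod, which encodes the collagen-binding fibromodulin (ENSMUSG00000041559, chromosome 1, 133964992 to 133976015), fell from 728 ± 183 to 75 ± 7.08 CPM (SD, n = 3; log2 -3.28, SE 0.188; edgeR's quasi-likelihood test, adjusted p = 4.58e-10). Eln, the elastin gene, fell (log2 -3.56), as did the collagen genes Col3a1 (-3.21), Col1a2 (-1.89) and Col1a1 (-1.50), and Fbln5 (-1.79) and Sparc (-1.57). Other large losses were H4c12 (-3.04), Wnt6 (-2.57) and Cdh22 (-2.49). In the extracellular matrix list 6 of 37 were higher and 16 lower, the same counts adjusted over the list alone. Of the fibroblast markers 0 of 12 were higher and 4 lower (0 and 5 adjusted over the list alone), among them Serpinf1 (-2.03) and Pdgfrb (-0.88). Camera called both (adjusted p = 2.96e-07 and 0.0107), and neither held with an estimated correlation (adjusted p = 0.364 for both). Each call was kept in the 9 other of 10 settings run, among them fry and leaving out each library. Eln stood at 97.1 CPM in Blank_4 against 33.6 and 43.01 in Blank_1 and Blank_2, and without Blank_4 the median log2 change of the 22 called matrix genes went from -0.89 to -0.71.

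Called lysosome and sterol genes were mostly lower in Dox and called endoplasmic reticulum (ER) stress and secretory genes mostly higher, though most members were not called. Of 40 lysosome and autophagy genes 0 were higher and 17 lower (1 and 18 adjusted over the list alone), including Glb1, the gene of senescence-associated beta-galactosidase, from 145 ± 4.95 to 88.9 ± 3.90 CPM (SD, n = 3), Tfeb (log2 -0.96), Hexa (-0.93) and Ctsa (-0.92). Of 27 genes of sterol synthesis and uptake 2 were higher and 12 lower (the same adjusted over the list alone), among them Fdps (-1.58), Tm7sf2 (-1.18), Ebp (-0.71) and Srebf2 (-0.51). Of 21 ER stress genes 7 were higher and 2 lower (10 and 2 adjusted over the list alone), with the sensor gene Ern1 (1.26) and the chaperone genes Hspa5 (1.14) and Hyou1 (0.94). Of 39 factors of the senescence-associated secretory phenotype (SASP) 10 were higher and 5 lower (the same adjusted over the list alone), with Spp1 (4.87-fold), Hbegf (4.65-fold), Plau (3.99-fold) and Csf1 (2.14-fold) higher. Camera called these lists with adjusted p of 2.54e-05 (lysosome), 4.1e-05 (sterol), 0.00753 (ER stress) and 0.0162 (SASP). None of these 4 calls held with an estimated correlation (adjusted p = 0.49, 0.37, 0.103 and 0.205). Each was kept in the 9 other of 10 settings run, among them fry and leaving out each library.

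**Figure D2:**
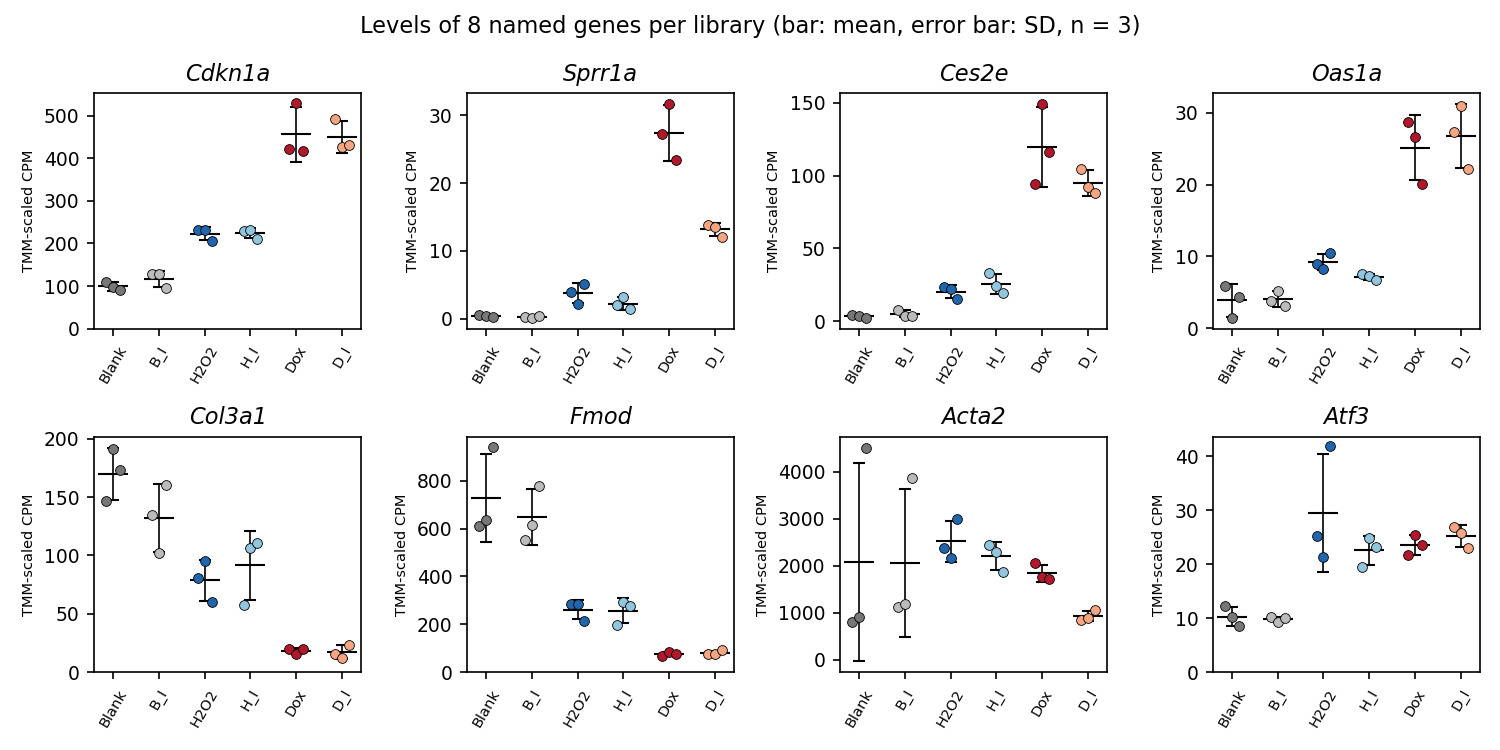
TMM-scaled CPM of Cdkn1a, Sprr1a, Ces2e, Oas1a, Col3a1, Fmod, Acta2 and Atf3 in each library (points), with the group mean (bar) and SD (error bar), n = 3. Cdkn1a averages 99.4 CPM in Blank, 223 in H2O2 and 456 in Dox, and Acta2 in Blank spans 806 to 4514.

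Lists tied to NK-cell recognition were not called by camera in Dox against Blank. Pvr, which encodes a ligand of the NK receptor DNAM-1, rose from 60.04 ± 2.17 to 82.1 ± 1.35 CPM (SD, n = 3; log2 0.45, edgeR's quasi-likelihood test, adjusted p = 0.00414). It was the higher of 2 called NK-cell activating ligands out of 11 (the same counts adjusted over the list alone). The other, the NKG2D ligand gene Raet1e (log2 -0.41), has close copies, and its call was lost without Blank_1, Blank_2, Dox_1 or Dox_2 (adjusted p 0.0592 to 0.149, and 0.0036 to 0.149 over all alternatives). Ulbp1 was not called (0.25, adjusted p = 0.565; -0.12 without Blank_4). Among 22 genes of MHC class I presentation 3 were higher and 3 lower (4 and 5 adjusted over the list alone), with H2-D1 (1.14) and H2-K1 (0.76) higher and B2m not called (0.14, adjusted p = 0.432; -0.00 without Blank_4). H2-D1 and H2-K1 have close copies, so their split of reads is uncertain. Among 11 death receptors and ligands 2 were higher and 1 lower (the same adjusted over the list alone), with Tnfrsf10b, a TRAIL receptor gene, at 1.27 and Tnfrsf1a at -0.58. Of 12 NK-cell inhibitory and checkpoint ligands 0 were higher and 2 lower (the same adjusted over the list alone). These were Cd276 (-0.43) and Cd47 (-0.42), the latter not called without any of the Blank_1, Blank_2, Dox_1, Dox_2 or Dox_3 libraries (adjusted p 0.09 to 0.25, and 7.73e-05 to 0.348 over all alternatives). Of 11 chemokines that attract NK cells 0 were higher and 1 lower (0 and 0 adjusted over the list alone), Cxcl16, whose call was lost without Blank_4 (0.124), Dox_1 (0.062) or Dox_3 (0.162), with 0.0149 to 0.162 over all alternatives. Ccl2, a chemokine gene fixed in advance, was not called (2.79 ± 0.627 against 1.11 ± 0.766 CPM, SD, n = 3; log2 1.31, adjusted p = 0.0904, 0.0185 to 0.403 over all alternatives), and without Blank_4 it stood at 0.82. Nor was the sterol gene Hmgcs1 (-0.40, 0.468, 0.0129 to 0.902 over all alternatives), with -0.76 without Blank_4, -0.09 without Blank_2 and -0.15 without Dox_2.

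The remaining lists were not called by camera in Dox against Blank either. Of 23 cell-cycle inhibitors and senescence regulators 1 was higher and 4 lower (3 and 5 adjusted over the list alone). Cdkn2a, the p16 and p19ARF gene, fell from 133 ± 25.2 to 88.7 ± 13.0 CPM (SD, n = 3; edgeR's quasi-likelihood test, adjusted p = 0.00992), a call lost without Dox_1 (0.0554) or Dox_3 (0.06), with 0.00145 to 0.06 over all alternatives. Lmnb1, the lamin B1 gene, was not called (log2 -0.11, adjusted p = 0.646). In the next counts the pair in brackets is adjusted over the list alone. Higher and lower were 4 and 1 of 25 NF-kB targets (4 and 1), with Tnfaip3 (1.18), and 6 and 8 of 38 DNA replication and E2F targets (6 and 9), with the chromatin assembly gene Chaf1b (-0.99). They were 4 and 1 of 22 contractile smooth muscle genes (4 and 1), with Mylk (0.99) and Tpm1 (0.57). The median of that list was 0.12 and its mean -0.13. Acta2 was not called (-0.18, adjusted p = 0.878, 1.97e-10 to 0.949 over all alternatives), and without Blank_4 it stood at 1.08 (0.117). Counts were 2 and 2 of 11 osteochondrogenic genes (3 and 3), and 6 and 7 of 33 NRF2 and antioxidant genes (7 and 7), with Hmox1 (0.64), Gstm1 (-2.08) and Ftl1 (-1.26). In the integrated stress response they were 7 and 5 of 31 (8 and 5), with Atf3 (1.19), Ddit3 (0.92) and Atf5 (-0.92).

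Further counts in Dox against Blank, with those adjusted over the list alone in brackets, were 1 higher and 4 lower of 13 lipid efflux and LXR targets (1 and 4). They were 3 and 2 of 22 BCL2 family genes and caspases (3 and 2), and 4 and 3 of 24 glycolysis and hypoxia genes (4 and 3). Immediate early genes counted 6 and 2 of 26 (8 and 3), and mitochondrially encoded genes 2 and 1 of 12 (2 and 1). Replication-dependent histones, whose reads are uncertain, counted 2 and 4 of 15 (2 and 6), with H2bc4 (1.99) and H1f2 (1.11) higher and a list median of -1.64. Macrophage markers counted 1 and 0 of 12 (1 and 0), the called member being Cd68 (2.07), and endothelial markers 0 and 0 of 12 (0 and 0). Only Ptprc and Il2rb of the NK and T lymphocyte markers were measured well enough to test, and 0 of these 2 were called (0 adjusted over the list alone).

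The comparison of H2O2 with Blank asks what the oxidant changed. Cdkn1a rose 2.24-fold, to 223 ± 15.2 CPM (SD, n = 3; log2 1.16, SE 0.124; edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.61e-05), and 4 of 30 p53 targets were higher and 0 lower (9 and 0 adjusted over the list alone). Of 31 integrated stress response genes 6 were called higher, among them Atf3 (log2 1.51), Ppp1r15a (0.80) and Atf4 (0.72), and 1 lower (12 and 1 adjusted over the list alone). Of 37 matrix genes 0 were higher and 8 lower (0 and 13 adjusted over the list alone), among them Fmod (-1.48), Col1a2 (-0.93), Col1a1 (-0.82), Fbln5 (-0.76) and Sparc (-0.75). The camera call of neither list held with an estimated correlation (adjusted p = 0.111 and 0.206). Both calls were kept in the 9 other of 10 settings run, fry among them. Ccl5, the gene of a chemokine that attracts lymphocytes (chromosome 11, 83416604 to 83421344), fell from 8.55 ± 2.01 to 0.965 ± 0.211 CPM (SD, n = 3; log2 -3.15, SE 0.31; adjusted p = 1.64e-05). Hmox1 (0.73), the heme oxygenase gene, rose and Gstm1 (-0.66), a glutathione transferase gene, fell.

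Other large rises with H2O2 were Ces2e (6.17-fold), H2bc4 (log2 1.75) and the protease inhibitor gene Slpi (3.08-fold), and Ptn (log2 -1.40) fell. H2bc4 is a histone gene, whose reads are uncertain. The secreted factors Spp1 (2.43-fold) and Hbegf (2.3-fold) and the mitotic kinase gene Aurka (1.46-fold) rose. Fitted on the 6 libraries alone, edgeR did not call H2bc4 (adjusted p = 0.121), Slpi (0.0763), Ptn (0.168), Spp1 (0.194), Hbegf (0.231) or Aurka (0.326). Of the 38 named genes called with H2O2, 4 kept their call in every setting, namely Ces2e, Ccl5, Fmod and Cdkn1a. Of the fixed genes Mki67 (-0.72, adjusted p = 0.123), Cdkn2a (-0.24, 0.548), Lmnb1 (-0.33, 0.304), Pvr (0.20, 0.451), Ulbp1 (0.06, 0.958), B2m (0.13, 0.661), H2-K1 (0.03, 0.952) and Acta2 (0.28, 0.902, 1.86e-10 to 0.977 over all alternatives) were not called by edgeR's quasi-likelihood test. Without Blank_4 Acta2 stood at 1.57 (0.106) and Ulbp1 at -0.27. Acta2 turned to -0.11 without Blank_1 and -0.08 without Blank_2, Ulbp1 to -0.04 without H2O2_2 and H2-K1 to -0.07 without H2O2_3. Ccl2 was not called (4.40 ± 3.05 CPM, SD, n = 3; log2 1.96, adjusted p = 0.0768, 0.0163 to 0.606 over all alternatives), with 1.23 without H2O2_3, nor was Hmgcs1 (-0.48, 0.592). Ddit3 was called (1.05, 0.0145), but not without H2O2_3 (0.83, 0.066; 0.000399 to 0.42 over all alternatives).

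Lists tied to NK-cell recognition were not called by camera in H2O2 against Blank. Of 22 genes of MHC class I presentation 0 were higher and 2 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.0742, and 0.268 with an estimated correlation). Erap1, which encodes a peptide-trimming enzyme, went from 13.74 ± 3.30 to 6.65 ± 1.42 CPM (SD, n = 3; log2 -1.04, edgeR's quasi-likelihood test, adjusted p = 0.023). Its call was lost without Blank_1 (0.0948), H2O2_1 (0.111) or H2O2_3 (0.065), with 0.00264 to 0.458 over all alternatives. Tap2, a peptide transporter gene, went from 29.58 ± 0.505 to 20.12 ± 0.669 CPM (SD, n = 3; log2 -0.56, 0.0498), a call lost without any of the 6 libraries (0.0801 to 0.133), with 0.0144 to 0.585 over all alternatives. Among 11 NK-cell activating ligands, 11 death receptors and ligands and 12 NK-cell inhibitory and checkpoint ligands 0 were called (1, 2 and 0 higher adjusted over the list alone). Of 11 chemokines that attract NK cells 0 were higher and 1, Ccl5, lower (1 and 1 adjusted over the list alone).

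In all, edgeR called 191 genes in H2O2 against Blank, 85 higher and 106 lower, and 44 changed over 2-fold. The count was 94 without Blank_1 and 109 without H2O2_1. It was 5 in the fit of the 6 libraries alone and 400 (180 higher, 220 lower) with DESeq2. The split moved to 81 higher and 67 lower with DESeq2 size factors, to 127 and 92 with upper-quartile scaling, to 396 and 108 by limma on log2(FPKM + 1) and to 410 and 105 on log2(FPKM + 0.1).

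Camera called 8 of the lists in H2O2 against Blank, and the p53 targets alone held with an estimated correlation (adjusted p = 3.07e-08, and 0.00061 with an estimated correlation). The integrated stress response (1.2e-10), extracellular matrix (8.44e-10) and immediate early genes (1.46e-05; 2 of 26 higher and 0 lower, 10 and 0 adjusted over the list alone) did not (adjusted p = 0.111, 0.206 and 0.199 with an estimated correlation). Each of these kept its call in the 9 other of 10 settings run, fry among them. The 4 other calls were weaker and each was lost without some library. Histones (2 of 15 higher, also adjusted over the list alone; 0.00822, and 0.325 with an estimated correlation) were not called without Blank_1 (0.18) or H2O2_3 (0.148), with 0.00201 to 0.325 over the alternatives. Fibroblast markers (1 of 12 lower, 2 adjusted over the list alone; 0.0132, and 0.268 with an estimated correlation) were not called without Blank_4 (0.0622) or H2O2_2 (0.136), with 0.000517 to 0.268 over the alternatives. The LXR targets (1 of 13 lower, 2 adjusted over the list alone; 0.0304, and 0.199 with an estimated correlation) were not called in H2O2 vs Blank without Blank_1 (0.0973), Blank_2 (0.0847) or H2O2_3 (0.0795), with 0.00252 to 0.199 over the alternatives. The DNA replication list (0 of 38 called, 6 lower adjusted over the list alone; 0.0383, and 0.325 with an estimated correlation) was not called without Blank_4 (0.325), H2O2_1 (0.0664) or H2O2_2 (0.0662), with 0.00704 to 0.325 over the alternatives. Of 48 interferon-stimulated genes 0 were called (1 higher adjusted over the list alone), and in the cell-cycle and mitosis list 1 of 35 was higher (2 adjusted over the list alone).

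Dox was compared with H2O2 to set the inducers side by side. Interferon-stimulated genes were higher in Dox, 23 of 48 with 0 lower (28 and 0 adjusted over the list alone), as were p53 targets (14 of 30 higher and 0 lower, the same adjusted over the list alone) and mitotic genes (17 of 35 higher and 0 lower, 19 and 0 adjusted over the list alone). Camera called them with adjusted p of 2.89e-15, 9.93e-10 and 1.39e-10, and all 3 held (0.0219, 0.000277 and 0.0219 with an estimated correlation). Under the naming rule Ccl5 (log2 3.31), Sprr1a (2.87) and Ces2e (2.56) were the genes furthest above H2O2. The largest falls under that rule were of the histone genes H4c12 (-3.12), H4c6 (-2.68) and H3c11 (-2.63), whose reads are uncertain. H4c6 was not called without Dox_1 (0.0537), Dox_2 (0.0652), Dox_3 (0.0995), H2O2_1 (0.0532) or H2O2_3 (0.0595), with 0.00232 to 0.0995 over all alternatives. H3c11 was not called without Dox_3 (0.101) or H2O2_3 (0.161), with 0.00169 to 0.161 over all alternatives. Called lysosome genes were lower in Dox, 14 of 40 with 0 higher (22 and 0 adjusted over the list alone). So were called sterol genes, 11 of 27 with 0 higher (14 and 0 adjusted over the list alone). Over all genes most members of both lists were not called. Their camera adjusted p of 1.62e-10 and 2.98e-09 did not hold (adjusted p = 0.25 and 0.193 with an estimated correlation). Camera also called ER stress genes higher (0.0232, and 0.187 with an estimated correlation), and histones (0.000171, and 0.274 with an estimated correlation), integrated stress response (0.000476, and 0.274 with an estimated correlation) and NRF2 genes (0.0281, and 0.187 with an estimated correlation) lower.

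By edgeR's quasi-likelihood test 1746 genes differed between Dox and H2O2, 900 higher and 846 lower in Dox. The count was 1080 without H2O2_3, 983 without Dox_1, 845 without Dox_3 and 2837 without Blank_4 and B_I_3. The split was 674 and 1036 with DESeq2 size factors, 768 and 1079 with upper-quartile scaling, 895 and 1272 with DESeq2, and 1331 and 879 by limma on log2(FPKM + 1). Of the 85 genes higher with H2O2, 74 were also higher with Dox, where independent lists would share 8.72, and of the 106 lower genes 90 were shared, where independent lists would share 12.1. No gene was called in opposite directions (0). Groups simulated without any effect against the same Blank libraries shared 0 calls in either direction, but they leave out the effects, so what the shared Blank libraries add to the overlap is not measured. Across genes the fold changes correlated with r = 0.521 (0.511 simulated), with a covariance of 0.275 against 0.102 simulated, a difference of 0.173. Genes are not independent replicates, and the 3 Blank libraries are too few to split, so part of the excess may come from the shared controls. Without Blank_1 the covariance was 0.755.

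B_I was compared with Blank for the effect of isoliensinine on cells without an inducer. Genes of the integrated stress response leaned higher, with 25 of 31 above 0, and so did genes of sterol synthesis and uptake, with 24 of 27 above 0, but 0 genes passed in either list, over all genes or adjusted over the list alone. Atf4, the transcription factor of that response, stood at 323 ± 6.48 against 253 ± 16.1 CPM (SD, n = 3; log2 0.35), Phgdh at 0.28 and the sterol gene Mvd at 0.36. Fos, an immediate early gene, stood at 4.88 ± 0.613 against 9.43 ± 0.475 CPM (SD, n = 3; log2 -0.95, SE 0.241), not called by edgeR's quasi-likelihood test (adjusted p = 0.917), and Egr1 at -0.45.

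Camera called 4 lists in B_I vs Blank, none with an estimated correlation or with fry: stress response (adjusted p = 2.67e-08, and 0.427 with an estimated correlation), sterol (1.3e-06, and 0.627 with an estimated correlation), lower matrix (0.00187, and 0.744 with an estimated correlation) and lower immediate early genes (0.0118, and 0.683 with an estimated correlation; 2 lower adjusted over the list alone). In B_I vs Blank without Blank_4 the sterol (0.136), matrix (0.818) and immediate early (0.0907) calls were lost. The matrix call was also lost without B_I_1 (0.0529) or B_I_2 (0.264), and the immediate early call without B_I_1 (0.0529). Over the alternatives the adjusted p ran from 9.26e-11 to 0.627 for sterol, 8.72e-09 to 0.818 for matrix and 0.013 to 0.683 for immediate early genes. EdgeR's quasi-likelihood test called 0 genes, with 640 at an unadjusted p under 0.05 where 669 would be expected by chance. DESeq2 called 1 and limma 0 at both pseudocounts, and without Blank_4 edgeR called 4.

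D_I was compared with Dox for the effect of isoliensinine on doxorubicin-treated cells. Lysosome genes leaned higher, with 34 of 40 above 0, among them the lysosomal calcium channel gene Mcoln1 (log2 0.32), Naglu (0.32) and Psap (0.26). Mitotic genes leaned lower, with 3 of 35 above 0, such as Cdk1 (-0.28) and Kif2c (-0.25), and contractile genes leaned lower, with 4 of 22 above 0. Acta2 stood at 930 ± 103 against 1836 ± 184 CPM (SD, n = 3; log2 -0.98, SE 0.591), and Tpm1 at 287 ± 9.55 against 408 ± 26.6 CPM (log2 -0.51). Neither was called by edgeR's quasi-likelihood test over all 18 libraries (adjusted p = 0.999 and 0.341). Acta2 was called in the fit of the 6 libraries of D_I and Dox alone (1.79e-05). It was also called without Blank_4, B_I_3, H2O2_3 and H_I_1 (1.2e-08), but not in every alternative. The immediate early genes Egr1 (0.57) and Junb (0.49) were not called over all 18 libraries (0.341 and 0.653). In the fit of the 6 libraries alone they were (0.000662 and 0.0069). Cdkn1a stood at 450 ± 36.9 against 456 ± 64.0 CPM (log2 -0.02, 0.999).

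Camera called those 4 lists in D_I against Dox, and none held with fry or an estimated correlation. The adjusted p was 1.89e-10 for lysosome, 1.86e-06 for mitosis, 9.53e-05 for immediate early genes and 0.000389 for contractile genes, and 0.375, 0.326, 0.375 and 0.375 with an estimated correlation. Adjusted over the list alone, 0 lysosome genes, 0 mitotic genes, 3 immediate early genes (higher) and 1 contractile gene (lower) passed, and over all genes 0 of each. EdgeR called 0 genes over all 18 libraries, with 556 at an unadjusted p under 0.05, DESeq2 20, and limma 1 at each pseudocount. Fitted alone, the 6 libraries had a coefficient of variation of 0.133 against 0.219 and gave 263 called genes, 109 higher and 154 lower.

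Genes from that fit of the 6 libraries were named after their values were seen. Lower ones with large changes included Sprr1a (27.4 ± 4.12 CPM in Dox and 13.2 ± 0.985 in D_I, SD, n = 3), Acta2 (log2 -0.998, SE 0.0838), Ccl5 (-0.94), Serpinb6b (-0.79) and Plod2 (-0.74). Among the higher ones were Mt1, a metallothionein gene (0.59), Egr1 (0.55), Tm7sf2 (0.53), Eva1b (0.49), C2cd2l (0.48) and Junb (0.47).

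H_I was compared with H2O2 for isoliensinine in oxidant-treated cells. Histone genes leaned lower, with 0 of 15 above 0 and H1f4 at 0.594 ± 0.196 against 3.70 ± 1.97 CPM (SD, n = 3; log2 -2.63, SE 0.706, edgeR's quasi-likelihood test, adjusted p = 0.288). Macrophage markers leaned higher, with 9 of 12 above 0. Of these, Ctss (2.14, adjusted p = 0.35) stood at 12.3 CPM in H_I_1 against 3.39 and 3.64 in H_I_2 and H_I_3. H_I_1 is also the library with the most colon and liver transcripts, with Alb, the liver albumin gene, at 230 CPM against 83.0 and 80.3. Sterol genes leaned higher, with 20 of 27 above 0, as in Hmgcs1 (0.85, adjusted p = 0.625) and Acat2 (0.35), and immediate early genes lower, with 7 of 26 above 0, as in Zfp36 (-0.51) and Egr1 (-0.36). Cdkn1a was at 224 ± 12.0 against 223 ± 15.2 CPM.

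Camera called these 4 lists in H_I vs H2O2, and none with fry or an estimated correlation. The adjusted p was 5.06e-07 for histones, 0.00701 for macrophage markers, 0.0163 for immediate early genes and 0.05 for sterol genes (below the threshold before rounding), and 0.656, 0.656, 0.656 and 0.8 with an estimated correlation. Macrophage markers were not called in H_I vs H2O2 without H_I_1 (0.098) or H2O2_2 (0.222). Immediate early genes were not called without H2O2_3 (0.723), nor sterol genes without H2O2_3 (0.723), H_I_1 (0.098) or H_I_2 (0.152). Over the alternatives the adjusted p ran from 3.04e-06 to 0.656 for macrophage markers, 0.000293 to 0.877 for immediate early and 5.19e-05 to 0.8 for sterol genes. Adjusted over the list alone 1 histone gene (lower), 1 macrophage marker (higher), 0 immediate early genes and 0 sterol genes passed, and over all genes 0 of each. EdgeR called 0 genes, with 915 at an unadjusted p under 0.05. DESeq2 called 67 (60 higher, 7 lower) and limma 0 at both pseudocounts, and without H2O2_3 edgeR called 10, all higher.

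The genes fixed for NK recognition were not called under isoliensinine by edgeR's quasi-likelihood test over all 18 libraries. In D_I against Dox, B2m stood at 1892 ± 52.1 against 1502 ± 123 CPM (SD, n = 3; log2 0.33, adjusted p = 0.844), H2-K1 at 0.28 (0.89), Pvr at 0.16 (0.999) and Ulbp1 at 0.02 (0.999). B2m and H2-K1 were called higher in the fit of these 6 libraries alone (0.32 and 0.26). Over all alternatives the adjusted p ran from 0.0124 to 1 for B2m and 0.0357 to 1 for H2-K1. In H_I against H2O2, B2m was at -0.17 (0.825), H2-K1 at 0.10 (0.906), Pvr at 0.01 (0.993) and Ulbp1 at -0.06 (0.987). In B_I against Blank, Ulbp1 was at -0.71 (0.967) and Pvr at -0.09 (0.998). Ulbp1 was called there without Blank_4 (-1.05, 0.0445; 0.00706 to 1 over all alternatives). Ccl2 was at -0.11 (0.998) in B_I, 0.20 (0.999) in D_I and -0.08 (0.988) in H_I. The median 95% half-width per gene was 0.474 to 0.482 on the log2 scale, over all genes and before adjustment. In the simulated data 17.9% to 28.4% of 1.5-fold and 52.2% to 62.7% of 2-fold changes were called in the isoliensinine comparisons. A missing call therefore does not exclude changes of these sizes or smaller in the genes named here.

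Doxorubicin's changes were present in the isoliensinine arm. Of the 2896 genes called in Dox against Blank, 1775 were called in the same direction in D_I against B_I, which share no library. Their median change along the doxorubicin direction was 0.67 in Dox and 0.54 in D_I, where counts simulated without an isoliensinine effect gave 0.637 on average (0.628 to 0.648). Genes picked instead in D_I against B_I had a median of 0.66 there and 0.62 in Dox against Blank (simulated 0.646, 0.628 to 0.662). In D_I against Dox, which shares the Dox libraries, 76.5% (jackknife SE 9.81) of the called genes had the opposite sign (simulated 61.5%, 60.3% to 63.1%). The covariance of these fold changes was -0.0937 against -0.0934 simulated without any effect and -0.101 without an isoliensinine effect. For the 191 genes of H2O2 the share opposite in H_I against H2O2 was 65.4% (jackknife SE 26.1, simulated 72.9%, 70.1% to 75%), and 69 of them were called in the same direction in H_I against B_I. The covariance of H2O2 against Blank with H_I against H2O2 was -0.252 against -0.103 simulated without any effect and -0.122 without an isoliensinine effect. With no shared library, Dox against Blank with D_I against B_I had 0.325 (0.00128 and 0.519), and H2O2 against Blank with H_I against B_I 0.05 (-4.97e-05 and 0.376). Between inducers, with no shared library, 38.6% (jackknife SE 14.8; simulated 49.9%, 47.7% to 52.3%) of Dox genes were opposite in H_I against H2O2. Of H2O2 genes 59.2% (jackknife SE 23.5, simulated 49.9%, 42.4% to 53.6%) were opposite in D_I against Dox. The simulations without an isoliensinine effect took the fitted group means as true effects, so the noise in those means was kept. They drew each gene independently, with no library standing apart, so their ranges may be too narrow. A gap between a value and its simulation therefore cannot be read as an effect of isoliensinine.

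No gene was called for a difference in the isoliensinine effect between backgrounds by the edgeR interaction test. The counts were 0, 0 and 0 for Dox minus Blank, H2O2 minus Blank and Dox minus H2O2, with 522, 813 and 1054 genes at an unadjusted p under 0.05. DESeq2 called 3, 2 and 4, and limma 0, 1 and 1 at each pseudocount. For Dox minus Blank the edgeR count was 4 without Blank_4 and 1 without B_I_3. Across genes, which are not independent replicates, the fold changes of the 3 isoliensinine comparisons correlated with r = 0.0521 (B_I and D_I, jackknife SE 0.0977), 0.0343 (B_I and H_I, 0.217) and 0.0115 (D_I and H_I, 0.15). The first was -0.0513 without D_I_3 and the second -0.193 without B_I_1. The mean effect over the 3 backgrounds called 0 genes in edgeR, with 680 at an unadjusted p under 0.05, a median half-width of 0.276 and 2 calls without the expression filter.

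**Figure D3:**
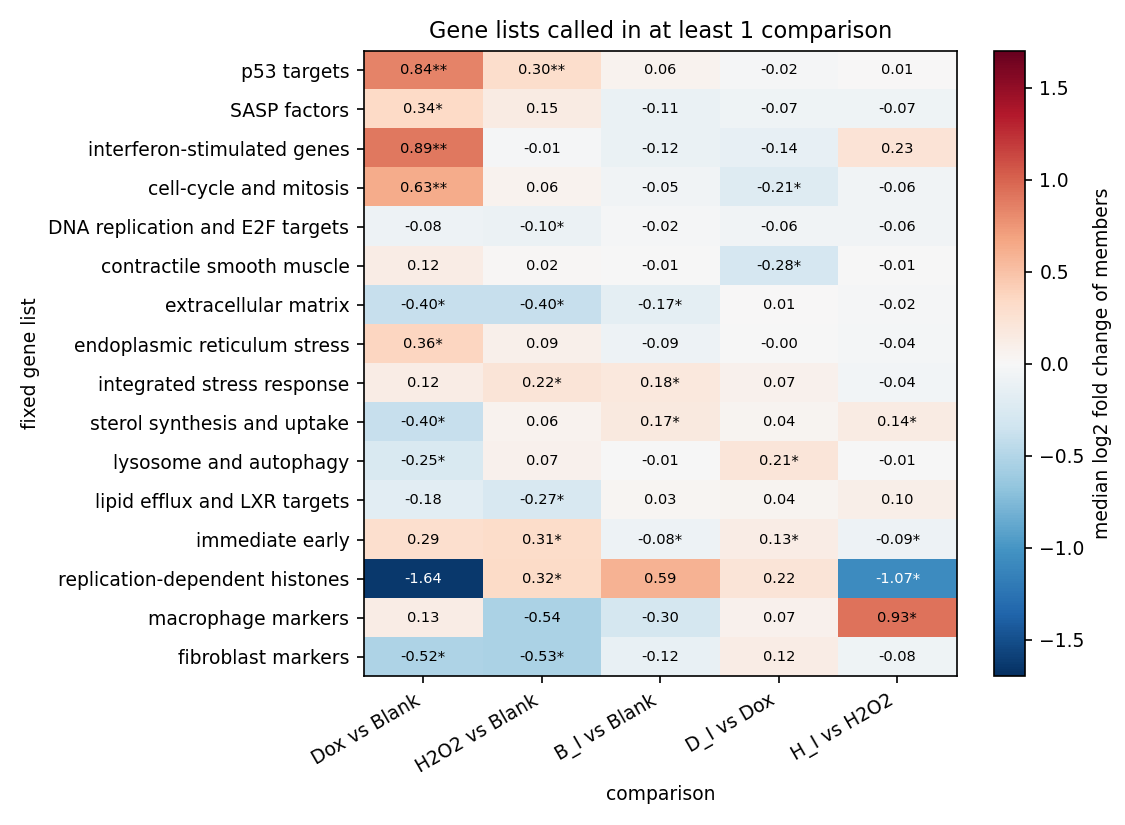
Median log2 fold change (colour and number) of each gene list called in at least 1 of 5 comparisons, with 1 asterisk for a camera call at the preset correlation and 2 for calls that hold with an estimated correlation. The p53 targets have medians of 0.84 in Dox and 0.30 in H2O2 against Blank, and no list in the isoliensinine columns has 2 asterisks.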

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

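The tests of lists between backgrounds were part of the plan, but reading them list by list was chosen after the results were seen. Each value here is a camera adjusted p at the preset correlation for a difference in the isoliensinine effect between backgrounds, tested as an interaction. None held with an estimated correlation or with fry, and edgeR's interaction test called 0 genes in each contrast.

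In D_I against Dox compared with B_I against Blank, 10 of 29 lists differed. The isoliensinine effect was higher in the Dox background for MHC class I presentation (0.00693), extracellular matrix (0.0448), lysosome and autophagy (4.32e-06) and immediate early genes (7.76e-07). It was lower there for cell-cycle and mitosis (0.0299), contractile smooth muscle (0.00693), integrated stress response (0.021), sterol synthesis and uptake (0.0344), glycolysis and hypoxia (0.0373) and mitochondrially encoded genes (0.0344). With an estimated correlation these had adjusted p of 0.234 to 0.662, and with fry 0.195 to 0.722. Blank_4 and B_I_3, which stood apart from their groups, are in this contrast. In B_I against Blank the sterol, matrix and immediate early calls were lost without Blank_4.

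Set against the Blank background, the H2O2 background differed in 4 lists. The effect was higher for interferon-stimulated genes (0.0181) and macrophage markers (0.0191), and lower for the integrated stress response (7.25e-08) and replication-dependent histones (1.25e-07). With an estimated correlation the adjusted p was 0.34 to 0.61, and with fry 0.325 to 0.401. The H_I_1 library, with the most colon and liver transcripts, is in this contrast, as are Blank_4, B_I_3 and H2O2_3.

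Between the Dox and H2O2 backgrounds 8 lists differed. The effect was higher with Dox for integrated stress response (0.00737), lysosome and autophagy (0.00011), immediate early genes (4.32e-05) and replication-dependent histones (0.000184). It was lower with Dox for cell-cycle inhibitors and senescence regulators (0.0258), interferon-stimulated genes (0.0129), contractile smooth muscle (0.00453) and mitochondrially encoded genes (0.0351). With an estimated correlation the adjusted p was 0.697 to 0.743, and with fry 0.356 to 0.585. H_I_1 and H2O2_3 are in this contrast as well. In H_I against H2O2 the immediate early call was lost without H2O2_3.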

How the results depend on the processing

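The fits without Blank_4 and B_I_3, or without these and H2O2_3 and H_I_1, and the comparisons of D_I and H_I with Blank and B_I and the mean isoliensinine effect, were chosen after seeing the data. No called gene that the text names changed direction in any alternative, while the correlations between isoliensinine comparisons, near 0, changed sign in some. Of the values per comparison 305 stayed and 94 moved, and of the values of named genes and comparisons 3729 stayed, 161 lost their call, 85 gained it and 122 moved. Of the named called genes 75 of 82 kept their call in every setting in Dox against Blank, 4 of 38 in H2O2 against Blank (Ces2e, Ccl5, Fmod and Cdkn1a) and 4 of 6 in Dox against H2O2. Depth and 3 libraries per group limit what can be called, with 50.7% to 62.7% of simulated 2-fold changes called (78.6% to 96.9% at 10 CPM or more). The correlation over only those genes called in an isoliensinine contrast gives no value, because 0 were called. Stricter thresholds lower counts by construction, and dropping libraries far from their groups lowers the spread by construction. The limma fits used FPKM, which divides by column totals with no TMM scaling. The TMM factors were 1.02 to 1.07 in Dox and 0.846 to 0.981 in Blank. For these fits and the other settings the cause of a change was not tested.

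By threshold, an adjusted p under 0.01 gave 1722 genes in Dox against Blank, 55 in H2O2 against Blank and 808 in Dox against H2O2, and a 2-fold minimum gave 620, 44 and 280. Without a filter on low counts the count was 1 in B_I against Blank, 2 in D_I against Dox, 1 for Dox minus Blank, 1 for Dox minus H2O2 and 2 for the mean effect. DESeq2 gave 400 in H2O2 against Blank, 1 in B_I against Blank, 20 in D_I against Dox, 67 in H_I against H2O2, and 3, 2 and 4 in the interactions Dox minus Blank, H2O2 minus Blank and Dox minus H2O2. Limma gave 504 and 515 in H2O2 against Blank at the pseudocounts 1 and 0.1, and 1 at each in D_I against Dox, H2O2 minus Blank and Dox minus H2O2. Only the groups compared gave 5 in H2O2 against Blank, 263 in D_I against Dox and 1 for Dox minus H2O2. The strict filter gave r = -0.179 for D_I and H_I.

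Without Blank_4 and B_I_3 the counts were 526 in H2O2 against Blank, 3 in B_I against Blank, 21 in D_I against Dox, 17 in H_I against H2O2, 2837 in Dox against H2O2, 8 for Dox minus Blank and 1 for Dox minus H2O2. Without all 4 libraries they were 689, 53, 184 and 58 in the first 4 of these, 76, 63 and 59 in the interactions, 3459 in D_I against Blank (2281 with all), 580 in H_I against Blank (323), 520 in H_I against B_I (195) and 32 for the mean effect, with 13 lists called in H2O2 against Blank and 8 in B_I against Blank. With an estimated correlation the lists called went from 9 to 3 in Dox against Blank, 8 to 1 in H2O2 against Blank and 4 to 0 in each isoliensinine comparison, and fry called 0 in those.

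Replicate numbers are not stated to pair libraries, and the correlations of deviations between libraries of equal number ran from -0.188 to 0.279. A replicate block gave 4 genes in D_I against Dox, 2 in H_I against H2O2, 3 for Dox minus Blank, 1 for Dox minus H2O2, 213 in H_I against Blank and 616 in H_I against B_I, while Dox against Blank had 2428.

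Leaving out each library gave 1876 (without Dox_3) to 2869 in Dox against Blank, 94 (Blank_1) to 259 (Blank_4) in H2O2 against Blank with 109 without H2O2_1, 0 to 4 (Blank_4) in B_I against Blank, 0 to 0 in D_I against Dox, 0 to 10 (H2O2_3) in H_I against H2O2, and 845 (Dox_3) to 1741 in Dox against H2O2 with 983 without Dox_1 and 1080 without H2O2_3. For Dox minus Blank it gave 0 to 4 (Blank_4) with 1 without B_I_3. D_I against Blank ran from 1446 (D_I_2) to 2171 with 1455 without D_I_1, and D_I against B_I (2518 with all) from 1615 (D_I_1) to 2545 with 1658 without D_I_2. H_I against Blank ran from 70 (H_I_1) to 311 with 156 without H_I_2 and 113 without H_I_3. H_I against B_I ran from 37 (H_I_1) to 424 (B_I_1) with 79 without B_I_2, 73 without B_I_3, 90 without H_I_2 and 63 without H_I_3. Lists called ran from 3 to 8 (B_I_3) in B_I against Blank, 4 to 7 (D_I_1) in D_I against Dox and 2 (H_I_1) to 8 (H_I_2) in H_I against H2O2. The correlations ran from -0.0513 (D_I_3) to 0.0486 for B_I and D_I, -0.193 (B_I_1) to 0.0966 for B_I and H_I, and -0.0667 to 0.119 for D_I and H_I, and the covariance of the inducers from 0.337 to 0.755 (Blank_1).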

Other observations

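Chosen only after the results were seen were the gene ontology terms, the test of Ces2e against colon transcripts, the tests of transcript length and of library totals, and the fits without libraries that stand apart. Called genes of the term cytoplasmic translation, which holds mostly ribosomal protein genes with close copies and so uncertain, were mostly lower with both inducers, though most members were not called. In Dox against Blank 1 of 78 was higher and 36 lower (median log2 -0.43), and in H2O2 against Blank 0 were higher and 9 lower (median -0.29). Camera gave cytoplasmic translation adjusted p of 2.95e-09 and 6.07e-12 over 1151 terms, and neither held (adjusted p = 0.919 and 0.895 with an estimated correlation). The ribosomal protein share was highest in Blank_4 (11.5%) among the Blank libraries.

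Camera called 12 of 1151 terms in Dox against Blank, 3 in H2O2 against Blank and 2 in B_I against Blank. It called 12 in D_I against Dox and 19 in H_I against H2O2. With an estimated correlation it called 0 in each. The terms named here are only a part of these, picked after the results were seen. Among those called in Dox against Blank were also collagen fibril organization (4 of 47 higher and 16 lower, camera adjusted p = 0.000272), glutathione metabolic process (2 of 40 higher and 11 lower, 0.0075), mitotic spindle assembly checkpoint signaling (12 of 30 higher and 0 lower, 0.0125) and response to virus (22 of 82 higher and 7 lower, 0.0287). None held (adjusted p = 0.849, 0.191, 0.849 and 0.849 with an estimated correlation). In D_I against Dox camera called lysosome organization higher (0.00847, and 0.782 with an estimated correlation) and mRNA splicing, via spliceosome lower (0.00626, and 0.325 with an estimated correlation), with 0 genes called in either. In H_I against H2O2 it called xenobiotic metabolic process (4.67e-11, and 0.708 with an estimated correlation) and hemostasis (0.000839, and 0.904 with an estimated correlation) higher. Genes of liver and gut belong to both terms, and H_I_1 held the most liver and colon transcripts.

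Colon and liver transcripts ran through all 18 libraries, with Muc2, Lypd8, Car1, Dmbt1 and Ceacam1 at 37.3 to 640 CPM in sum and Alb at 230 CPM in H_I_1. Of 31 other colon genes 29 had at least 20 counts, and they followed that sum with a median Spearman rho of 0.744; for 25 other liver genes and Alb it was 0.738, and 4 and 6 of them reached 1 CPM in every library, with 0 of either set in the fixed lists. These values go with reads from colon and liver tissue outside the cell line, as a hypothesis. Over the sum of the 5 and the 29 colon genes, the permutation p between groups without H_I_1 was 0.294. H_I_1 stood at 2.53 times the next library of its group. Both met the bounds set beforehand against expression by the cells in response to the treatments. They do not decide it, since so few libraries per group can hide a difference and the sum holds the genes that first showed the pattern. Expression by the cells whatever the treatment was not tested. That the rise of Ces2e with doxorubicin is part of this signal is argued against: at the highest ratio of Ces2e to the colon sum in Blank, that sum would bring at most 9.72% of Ces2e in a Dox library, and Ces2e had a Spearman rho of 0.207 with it (permutation p = 0.406, r = -0.0298 with p = 0.929, 0.131 without H_I_1 and H_I_3, 4 relations tested, adjusted p = 0.406 and 0.929). Where the reads entered, in the cells, the RNA or the sequencing, was not tested.

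No gene was called for isoliensinine in any background by edgeR over the 18 libraries, against 640, 556 and 915 genes at an unadjusted p under 0.05 and 1, 20 and 67 by DESeq2. A spread inflated by libraries that stand apart may account for part of this. Without Blank_4, B_I_3, H2O2_3 and H_I_1, none of which is in D_I or Dox, D_I against Dox called 184 genes. Dropping far libraries lowers the spread pooled over groups by construction. The fit of the 6 libraries of D_I and Dox alone called 263, of which 175 were among the 184. Its coefficient of variation was 0.133 against 0.219. Fits of only the groups compared called 0 in B_I against Blank and 0 in H_I against H2O2. A test too weak for 2-fold changes stays open, since 62.7% of simulated 2-fold changes were called in D_I against Dox, between the bounds of 50% and 80% set beforehand, with 88.9% (40 of 45) at 10 CPM or more. An effect too small to call but shared by the backgrounds stays open too, since the highest correlation between isoliensinine comparisons was 0.0521 with a jackknife SE of 0.0977. A biological difference between the backgrounds is untested beyond the interactions.

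Blank_4 and B_I_3 stood apart from their groups in their TMM factors of 0.846 and 0.868, against 0.945 to 0.983 in the others of Blank and B_I. Fewer counts in these libraries are argued against, since the largest ratio of totals to others of their groups was 1.09. A bias by transcript length stays open, since the Spearman rho across genes between the deviation and gene length was -0.213, between the bounds set for it. The loss of matrix transcripts with doxorubicin may rest in part on Blank_4: the median of the 22 called genes was -0.89 with it and -0.71 without it, a ratio of 1.26, with 19 of them still called. No biological explanation was tested for these libraries, whose labels match the rest of their groups.

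Other splits of the libraries were counted for each comparison. With 10 splits of 6 libraries a share under 0.05 cannot be reached. The number of splits with as many called genes as the real one was 1 for Dox against Blank (2896 genes, highest other split 0), 1 for H2O2 against Blank (191, highest other 39) and 1 for Dox against H2O2 (1746, highest other 0). It was 10 for B_I against Blank (0, highest other 2193), 10 for D_I against Dox (0, highest other 0) and 10 for H_I against H2O2 (0, highest other 0). The split with 2193 genes set Blank_4, B_I_2 and B_I_3 against the rest, which points to a structure of the samples other than treatment. For the interactions, 40 of 40 drawn splits gave as many as the real 0 in each contrast, with highest others of 0, 1836 and 0. With a real count of 0 every split gives as many, so in the 3 isoliensinine comparisons and 3 interactions the share says nothing about chance. The split with 1836 again put Blank_4, B_I_2 and B_I_3 in an arm. Other H2O2 minus Blank splits that set these against Blank_1, Blank_2 and B_I_1 gave 887, 3 or 0 genes. The Dox minus Blank splits that did so gave 0.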
